A study of Mus musculus with 12 samples.

How the data were processed

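RNA of the mouse mesenchymal cell line C3H/10T1/2 was sequenced in 12 libraries, 3 in each of 4 groups. The cells had been transfected transiently with a plasmid, and RNA was collected 3 days later. The libraries were made with QuantSeq 3' mRNA FWD, which reads mainly the 3' ends of polyadenylated transcripts. According to the submitters' notes, reads were checked with FastQC 0.11.5, aligned to GRCm38 with STAR 2.5.2a and counted with HTSeq 0.6.0. The deposited values are counts per gene without normalisation, in 1 file per library. The counting mode, the strand setting and the annotation release are not given in the sources used here, so reads from overlapping genes on the opposite strand cannot be excluded for single genes. The files list 47643 genes, of which 47224 were given a symbol from GENCODE M21, which is on the same build. Lines that hold no gene, mainly reads with more than 1 alignment, made up 52.2% to 54.4% of the records of a library and were left out of all totals. Related genes, such as Ifit3 and Ifit3b, Mx1 and Mx2 or H2-K1 and H2-D1, are therefore measured only by the reads that told them apart. How many reads each of them lost in this way was not tested and may differ between them.

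Groups follow the labels: BMP2ADV, the reference, and the hybrid plasmids BMP2ADV20a, BMP2ADV148b and BMP2ADV590. The labels do not say whether the 3 libraries of a group came from separate cultures, so the spread behind each p-value may be smaller than that between independent experiments. No untransfected or mock-transfected group was analysed here, so the effect of BMP2 itself was not tested. One model with a mean for each group was fitted to all 12 libraries with edgeR 4.0.16 in R 4.3.3, with TMM scaling, genes kept by filterByExpr and the quasi-likelihood F-test. It tested 13229 genes, with a common biological coefficient of variation of 0.117. P-values were adjusted by Benjamini-Hochberg and called at 0.05. The contrasts were each hybrid group against BMP2ADV, each pair of hybrid groups, and all 4 groups at once. Each log2 fold change is given as the first group minus the second, from the edgeR fit at its default prior count. A prior count of 2 was used only for the log2 CPM behind the list tests, the seed tests and the principal components. Levels are normalised counts-per-million (CPM), as mean ± SD of 3 libraries, and intervals are 95% intervals of the fit. A total of 0 was taken to allow up to 3 counts over a group. That limit covers counting error only, since amplified reads carry no molecular tags here, while the intervals of the fit also hold the spread between libraries.

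The groups, contrasts, gene lists, seed sites and the rule for naming genes were set before the data were examined. Of 32 gene lists, 27 had at least 5 tested members and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, against an estimated correlation and with fry as alternatives. They were osteoblast, chondrocyte, adipocyte, contractile fibroblast, BMP-SMAD targets, BMP pathway components, interferon response, MHC class I presentation, NF-kB inflammatory genes, mitosis, DNA replication, p53 response, unfolded protein response, cholesterol synthesis, hypoxia and glycolysis, extracellular matrix, matrix remodelling, Wnt, Notch and TGF-beta targets, lysosome, immediate early genes, mitochondrial transcripts, ribosomal proteins and candidate targets of each of the 3 miRNAs. Markers of skeletal muscle, macrophages, endothelium, epithelium and neural cells had too few tested members and were only counted. Always named were Bmp2, Mir17hg, Eif4h, Nog, Smad7, Pparg, Bambi and Crim1. For each hybrid group against BMP2ADV, the rule then took the 8 largest rises and the 8 largest falls among called genes with at least 10 CPM in 1 of the groups and no overlap between libraries, and up to 4 called members of each list by smallest p. For pairs of hybrid groups it took 5 in each direction. Gene models without an established name were counted, not named. The result of 1 gene that the rule takes is not reported here.

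Seed sites were 7-mers complementary to miRNA positions 2 to 8, searched in the longest annotated 3' UTR of the 11583 tested genes that have one (median length 1220 bases). The arm of miR-590 on the plasmid is not given in the sources used here, so both arms were searched. Site genes were compared with the other genes by camera, and the shift was ranked among up to 1000 random 7-mers with a similar number of site genes.

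The edgeR steps were tested on simulated data with the depth of each library and the dispersions of the fit to all 12 libraries. Changes were put into BMP2ADV590 and tested against BMP2ADV. The changed genes counted here were drawn from those above a low mean CPM, so recovery of the scarcest genes was not tested. Of 67 genes changed 1.5-fold, 33 were recovered, as were 48 of 67 changed 2-fold and 64 of 66 changed 4-fold, while 6 of 11009 unchanged genes were called. The alternatives set in advance were DESeq2 1.42.0, limma-voom, other scaling factors, no filter and a stricter filter (at least 10 counts in every library of a group), a fit of only the compared groups, a term for the replicate number, 8-mer sites and leaving out each library in turn. Added after the data had been seen were the removal of Gm42418 and the mitochondrial genes, and leaving out each library for the gene lists and seed sites.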

Results

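The transcriptomes of C3H/10T1/2 cells, a mouse embryonic line of fibroblast shape that can be turned towards cartilage, bone or fat, were compared 3 days after transfection. The reference plasmid, BMP2ADV, encodes bone morphogenetic protein 2 (BMP2), a growth factor that drives bone and cartilage formation. The hybrid plasmids are named after the miRNA they were built to express along with BMP2: miR-20a, miR-148b or miR-590. The series addresses whether such hybrid vectors could serve bone regeneration. Each of the 12 libraries held 9236431 to 14727288 gene counts and 17086 to 18055 genes above 0. The 3 libraries of a group summed to 33469711 gene counts in BMP2ADV, 39151507 in BMP2ADV20a, 28286785 in BMP2ADV148b and 35572113 in BMP2ADV590. Gm42418, a gene model that overlaps ribosomal RNA sequence, took 4.07% to 10.0% of gene counts and mitochondrial transcripts 1.68% to 2.32%. The first principal component, with 18.0% of the variance, placed the BMP2ADV590 libraries at 21.8 to 30.2 and all others at -25.3 to 6.42. BMP2ADV590 replicate 2 stood apart from its group on the component that held 11.7% of the variance, at -23.4 against 22.6 and 9.63.

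The plasmids left a direct trace for 1 of the miRNAs. Mir148b (ENSMUSG00000065560, GRCm38 chromosome 15, 103285125 to 103285221), which lies within the span of Copz1, had 211, 215 and 204 counts in the BMP2ADV148b libraries and 0 in the other 9. That is at least 248-fold higher than the limit of 3 counts over the BMP2ADV group. Mir20a (ENSMUSG00000065442) had 0 counts in all 12 libraries and Mir590 is not in the annotation used, so the other hybrid labels could not be checked in this way. Mir17hg, the host transcript of miR-20a, and Eif4h, the host gene of miR-590, passed the test in none of the comparisons with BMP2ADV. Bmp2 (ENSMUSG00000027358, chromosome 2, 133552159 to 133562885) was scarce in every group, at 1.30 ± 0.527 CPM in BMP2ADV, 3.40 ± 0.693 in BMP2ADV20a, 5.36 ± 2.58 in BMP2ADV148b and 5.05 ± 0.687 in BMP2ADV590. It rose in BMP2ADV590 (log2 fold change 1.91, SE 0.381, adjusted p = 0.0021) and in BMP2ADV148b (2.00, SE 0.383, adjusted p = 0.0326). Its value in BMP2ADV20a was 1.35 (SE 0.387, adjusted p = 0.16). The call in BMP2ADV148b was lost without any 1 of the BMP2ADV libraries or without BMP2ADV148b replicate 2 or 3, with adjusted p up to 0.212. The log2 fold change of Bmp2 in BMP2ADV148b against BMP2ADV also missed the threshold under limma-voom (adjusted p = 0.106), and DESeq2 did not call it, since its own filter on low counts gave the gene no adjusted p. The species and the 3' end of the BMP2 cassette are not given in the sources used here, so these reads cannot be assigned to the plasmid or to the cell's own gene.

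**Figure D1:**
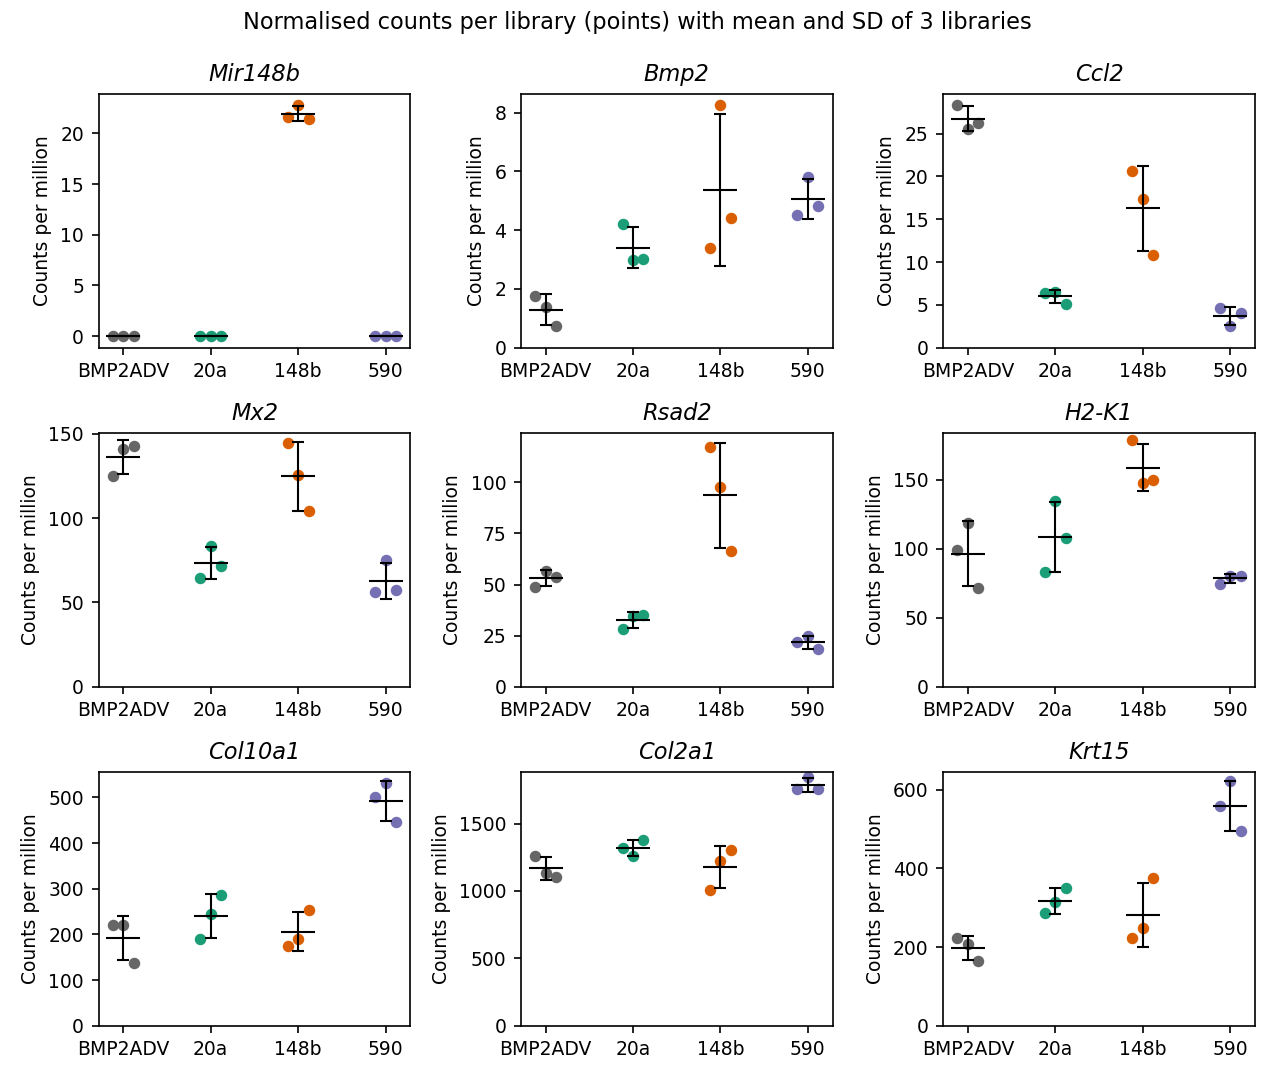
Normalised counts-per-million of 9 genes in each library (points), with the mean and SD of the 3 libraries of each group. Mir148b is seen in BMP2ADV148b only, Ccl2 and Mx2 are lowest in BMP2ADV590, and Col10a1, Col2a1 and Krt15 are highest there.

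With miR-20a on the plasmid, some inflammatory genes fell. Ccl2 (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453), which encodes a chemokine that draws monocytes, dropped from 26.8 ± 1.46 to 5.98 ± 0.799 CPM (log2 fold change -2.15, SE 0.215, adjusted p = 8.02e-06). The chemokine gene Cxcl1 (ENSMUSG00000029380, chromosome 5) fell from 17.7 ± 3.95 to 5.73 ± 0.483 CPM (-1.63, SE 0.202, adjusted p = 0.000199) and Ccl7 from 16.6 ± 2.00 to 5.67 ± 0.781 (-1.55, SE 0.216, adjusted p = 0.000642). The antiviral genes Mx2 and Mx1 were also lower, and keratin and matrix genes were among the few that rose. In all, 13 genes were higher and 50 lower in BMP2ADV20a than in BMP2ADV, out of 1306 with an unadjusted p under 0.05. The count rests on every library of both groups. It was 27, 18 and 31 without BMP2ADV replicate 1, 2 and 3, and 25, 26 and 20 without BMP2ADV20a replicate 1, 2 and 3. Without BMP2ADV590 replicate 2 it was 108.

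Of 16 NF-kB inflammatory genes, 5 fell and none rose, with 11 lower adjusted over the list alone (median log2 fold change -0.84, camera adjusted p = 1.37e-14). This call held with an estimated correlation (adjusted p = 0.0462). Besides the chemokines, Tnfaip3, which encodes a brake on NF-kB signalling, fell by 1.70 (adjusted p = 0.00586) and Relb, named after its values were seen, fell by 0.90. Of 29 interferon response genes, 4 fell and none rose, and adjusted over the list alone 11 were lower and 1 higher (median -0.21, camera adjusted p = 2.28e-08, adjusted p = 0.37 with an estimated correlation). Mx2 (ENSMUSG00000023341, chromosome 16) fell from 136 ± 9.95 to 73.3 ± 9.66 CPM (-0.89, SE 0.122, adjusted p = 0.000642) and Mx1 from 35.05 ± 3.24 to 17.4 ± 1.55 (-1.01, SE 0.162, adjusted p = 0.0022). Cxcl10 fell by 0.90 (adjusted p = 0.018) and Rsad2 by 0.70 (adjusted p = 0.0355). Both calls were lost without BMP2ADV replicate 2 or BMP2ADV20a replicate 1 or 3, which left 2 interferon genes called as lower. The adjusted p of Cxcl10 rose to at most 0.164. Rsad2 lost its call without 7 of the libraries in all (adjusted p up to 0.218). Of 18 p53 response genes, 3 fell (Mdm2 -0.53, the death gene Bbc3 -0.60 and Plk2 -0.42), against 1 higher and 7 lower adjusted over the list alone (median -0.16, camera adjusted p = 0.0007, adjusted p = 0.208 with an estimated correlation). None of these 3 calls held without BMP2ADV replicate 1 or 2 or BMP2ADV20a replicate 1 or 2 (up to 0.214). Among called genes with at least 10 CPM, large falls outside these lists were those of Bhlhe41 and Noct, linked to the circadian clock (-1.34 and -1.27), the stress gene Gadd45a (-1.15), Maff (-1.08) and the interferon-inducible Ifi207 (-1.03).

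Sparc, which encodes an abundant bone matrix protein, rose to 7712 ± 431 CPM against 6051 ± 486 (0.35, SE 0.0783, adjusted p = 0.041), a call lost without 6 of the libraries (up to 0.257). It was the 1 member called in both the osteoblast list (16 tested, 4 higher adjusted over the list alone, median 0.12) and the extracellular matrix list (18 tested, 3 higher adjusted over the list alone, median 0.10). Both lists had a camera adjusted p of 0.0097, with adjusted p = 0.16 and 0.423 with an estimated correlation. The osteoblast call was lost without BMP2ADV20a replicate 1 (adjusted p = 0.0552) and the matrix call without BMP2ADV replicate 2 (0.0577). The epidermal keratin genes Krt15 (317 ± 32.1 against 198 ± 30.3 CPM, log2 fold change 0.68) and Krt16 (0.82), together with Anxa8 (0.64), Cdsn (0.61), Hspb1 (0.81), the matrix proteoglycan gene Fmod (0.60), Fibin (0.64) and Mmp11 (0.71), also rose. Of the 28 named genes called, 8 kept the call whichever library was left out (Bhlhe41, Ccl2, Ccl7, Cxcl1, Gadd45a, Mx1, Mx2 and Tnfaip3). Krt15 and Krt16 did not, with adjusted p up to 0.18 and 0.234.

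The chondrocyte list as a whole was higher in BMP2ADV20a (12 tested, median 0.18, camera adjusted p = 0.0423) although edgeR called 0 of its members, with 3 at an unadjusted p under 0.05 and 0 called by DESeq2, by limma-voom or adjusted over the list alone. Its call was lost with an estimated correlation (adjusted p = 0.719) and without BMP2ADV replicate 2 or 3, BMP2ADV20a replicate 3, BMP2ADV148b replicate 2 or BMP2ADV590 replicate 1 (up to 0.505). Mitosis, DNA replication and immediate early genes shifted down as lists, with medians of -0.09, -0.08 and -0.21 and camera adjusted p of 0.0097, 0.0423 and 0.0097. Here edgeR, DESeq2 and limma-voom called 0 members each, with 2, 2 and 4 at an unadjusted p under 0.05. With an estimated correlation the adjusted p was 0.284, 0.597 and 0.267. Of the 9 list calls in BMP2ADV20a, fry, which tests whether the genes of a list move on balance in 1 direction, kept NF-kB, p53 response and osteoblast (adjusted p = 0.0022, 0.0391 and 0.0436). It did not call the interferon (0.136), extracellular matrix (0.165), mitosis (0.0751), DNA replication (0.251), immediate early (0.0751) or chondrocyte (0.545) lists. The mitosis call was lost without BMP2ADV replicate 3 (0.159), the immediate early call without BMP2ADV20a replicate 2 (0.0846) and the DNA replication call without 7 of the libraries (up to 0.457). The other 18 lists were not called, with camera adjusted p from 0.0892 to 0.968. Among genes of the matrix remodelling list, Mmp11 rose and Mmp9, which encodes a gelatinase, went from 1.41 ± 0.669 to 0.0483 ± 0.0419 CPM. Its mean (-0.27) and median (0.07) differ in sign. Csf1 (-0.57) and Trib3 (-0.52), picked by other lists, fell as well.

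With miR-148b on the plasmid, some genes of antiviral defence and antigen presentation rose. Ly6e (ENSMUSG00000022587, chromosome 15, 74955051 to 74959905), an interferon-induced membrane protein gene, went from 170 ± 23.7 to 277 ± 19.5 CPM (log2 fold change 0.70, SE 0.0994, adjusted p = 0.00188). The class I heavy chain gene H2-K1 (ENSMUSG00000061232, chromosome 17) went from 96.5 ± 23.6 to 159 ± 17.4 CPM (0.72, SE 0.146, adjusted p = 0.0391), and the antiviral gene Rsad2 (ENSMUSG00000020641, chromosome 12) from 53.02 ± 3.89 to 93.8 ± 25.6 (0.82, SE 0.149, adjusted p = 0.0178). Cyp26b1, which encodes an enzyme that breaks down retinoic acid, rose from 207 ± 36.2 to 349 ± 76.0 CPM (0.75, adjusted p = 0.0178). In all, 28 genes were higher and 5 lower than in BMP2ADV, out of 1115 with an unadjusted p under 0.05. The count was 6, 12 and 3 without BMP2ADV replicate 1, 2 and 3, 20, 4 and 5 without BMP2ADV148b replicate 1, 2 and 3, and 13, 20 and 17 without BMP2ADV20a replicate 1, 2 and 3. It was 16 without BMP2ADV590 replicate 3 and 60 without BMP2ADV590 replicate 2, and of the 18 named genes called only Ly6e and Mir148b kept the call whichever library was left out.

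Of 29 interferon response genes, 3 rose and none fell, with 16 higher adjusted over the list alone (median 0.29, camera adjusted p = 2.41e-11, adjusted p = 0.364 with an estimated correlation). They were Ifit3b (0.52), Rsad2 and Cxcl10 (0.80, 86.4 ± 30.2 against 49.6 ± 6.26 CPM). Leaving out single libraries raised their adjusted p to at most 0.187, 0.139 and 0.278. The number that rose was 0, 1 and 0 without BMP2ADV replicate 1, 2 and 3, 0 and 1 without BMP2ADV148b replicate 1 and 2, and 7 and 8 without BMP2ADV590 replicate 1 and 2. Of 10 MHC class I presentation genes, 4 rose and none fell, with 8 higher adjusted over the list alone (median 0.39, camera adjusted p = 4.78e-09, adjusted p = 0.314 with an estimated correlation). Besides H2-K1 these were H2-D1 (0.41) and the immunoproteasome subunit genes Psmb8 and Psmb10 (0.72 and 0.50). Neither list was called by fry (adjusted p = 0.118 and 0.0805). Under camera with the preset correlation both calls held whichever library was left out, with adjusted p of at most 4.33e-06 and 3.16e-06, while each of the 4 MHC class I genes lost its call without BMP2ADV replicate 1 or 3 or any 1 of the BMP2ADV148b libraries, with adjusted p up to 0.352. Of these genes, 2, 2 and 1 were called without BMP2ADV20a replicate 1, 2 and 3, and 1 without BMP2ADV590 replicate 3.

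In the unfolded protein response list (18 tested) Hspa5, the main chaperone of the endoplasmic reticulum, and Sdf2l1 rose by 0.32 and 0.85, with 4 higher and 1 lower adjusted over the list alone (median 0.17, camera adjusted p = 0.0258, adjusted p = 0.443 with an estimated correlation). This list lost its call without BMP2ADV replicate 1 or 2 or BMP2ADV148b replicate 1 or 2 (up to 0.15), and both genes lost their calls when any 1 BMP2ADV or BMP2ADV148b library was left out (up to 0.187). Vegfa, the vessel growth factor gene, fell from 27.9 ± 1.63 to 17.8 ± 2.29 CPM (-0.64, adjusted p = 0.0465), a call lost without 10 of the libraries (up to 0.265), and Mid1ip1 (-0.57), Tmem123 (-0.45) and Gadd45b (-0.44) fell with it. Mmp11 rose by 0.66. The contractile fibroblast, mitosis and immediate early lists were lower as a whole, with medians of -0.16, -0.10 and -0.11 and camera adjusted p of 0.0141, 0.0258 and 0.0305. With an estimated correlation the adjusted p was 0.314, 0.364 and 0.364. In each of these lists edgeR, DESeq2 and limma-voom called 0 members, with 3, 2 and 2 at an unadjusted p under 0.05 and 2, 0 and 1 lower adjusted over the list alone. The contractile call was lost without BMP2ADV148b replicate 3 (0.0744), the mitosis call without BMP2ADV replicate 2 or 3 or BMP2ADV148b replicate 2 or 3 (up to 0.237), and the immediate early call without any 1 of the BMP2ADV libraries or BMP2ADV148b replicate 1 or 3 (up to 0.0964). By fry the unfolded protein response (adjusted p = 0.118), contractile (0.107), mitosis (0.121) and immediate early (0.159) lists were not called either, so none of the 6 list calls in BMP2ADV148b held there. The remaining 21 lists were not called (camera adjusted p 0.0536 to 0.99).

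With miR-590 on the plasmid, 578 genes rose and 515 fell against BMP2ADV, out of 2809 with an unadjusted p under 0.05. Cartilage genes rose together. Col10a1 (ENSMUSG00000039462, chromosome 10, 34389981 to 34397085), the collagen gene of hypertrophic cartilage, reached 493 ± 43.7 CPM against 192 ± 48.5 (log2 fold change 1.36, SE 0.155, adjusted p = 7.32e-06). Sox9 (ENSMUSG00000000567, chromosome 11, 112782224 to 112787760), the master regulator of chondrocytes, reached 2940 ± 224 CPM against 1727 ± 210 (0.77, SE 0.1, adjusted p = 2.87e-05), and Col2a1 (ENSMUSG00000022483, chromosome 15), the main collagen gene of cartilage, 1785 ± 52.0 against 1167 ± 83.0 (0.61, SE 0.0832, adjusted p = 4.26e-05). Some inflammatory, interferon and cell division genes fell. Of the 13 list calls in this group, 0 held with an estimated correlation (lowest camera adjusted p = 0.0641). Without BMP2ADV replicate 2 or 3 the count was 678 or 565, and without BMP2ADV590 replicate 2, the library that stood apart, it was 935. Over all tested genes, 25.1% had no overlap between the 3 libraries of each group, where chance gives 10%.

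Of 12 chondrocyte genes, 11 rose and none fell, with 12 higher adjusted over the list alone (median 0.93, camera adjusted p = 1.43e-10, adjusted p = 0.119 with an estimated correlation). Hapln1, which encodes a protein that anchors the cartilage matrix, reached 217 ± 9.85 CPM against 91.9 ± 22.7 (1.23, SE 0.142, adjusted p = 7.96e-06). Of 15 BMP-SMAD target genes, 6 rose and none fell, and 6 were higher adjusted over the list alone (median 0.24, camera adjusted p = 2.77e-05, adjusted p = 0.096 with an estimated correlation). Among them, Hey1 rose by 0.93 (162 ± 6.45 against 84.9 ± 9.24 CPM), the BMP decoy receptor gene Bambi by 0.69, Dlx5 by 0.61, the inhibitory Smad6 by 0.46 and the secreted BMP antagonist gene Nog by 1.58 (4.28 ± 1.02 against 1.42 ± 0.190 CPM), and Msx1, named after its values were seen, rose too. Nog lost its call without any 1 of the BMP2ADV libraries or without BMP2ADV590 replicate 1 or 3 (up to 0.155), and Smad6 without BMP2ADV590 replicate 1 (0.064), where 3 BMP-SMAD targets were called as higher. The osteoblast list (16 tested, median 0.36, camera adjusted p = 0.0178, adjusted p = 0.096 with an estimated correlation) had 3 rises and no falls, and 3 higher adjusted over the list alone. They were Pth1r, the parathyroid hormone receptor gene (1.12), Dlx5 and Sparc (0.33). The list lost its call without BMP2ADV replicate 1 or BMP2ADV590 replicate 1 (up to 0.0516) and Sparc without BMP2ADV replicate 2 (0.0731).

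Of 21 BMP pathway components, Bmp2, the receptor gene Bmpr2 (0.40), Nog, Bambi and the antagonist gene Grem1 (0.52) rose and Bmp4 fell from 192 ± 17.0 to 133 ± 26.8 CPM (-0.53, SE 0.104, adjusted p = 0.00181), and the list as a whole was not called (camera adjusted p = 0.604). Extracellular matrix genes rose, 8 of 18 with no fall and 12 higher adjusted over the list alone (median 0.25, camera adjusted p = 4.02e-05, adjusted p = 0.119 with an estimated correlation), among them Col6a2 (0.85), Col6a1 (0.77) and the elastin gene Eln (0.64), which lost its call without BMP2ADV replicate 2 (0.0515). The number of matrix genes that rose was 3 and 4 without BMP2ADV replicate 2 and 3. In the matrix remodelling list 4 of 13 rose, with Mmp11 at 112 ± 17.0 CPM against 43.1 ± 3.09 (1.38, SE 0.135, adjusted p = 1.1e-06), the inhibitor gene Timp3 (0.58) and Mmp2 (0.51), and 4 fell, with Adamts1 (-0.46) among them (camera adjusted p = 0.927).

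Among called genes with at least 10 CPM and no overlap between libraries, keratins made up 5 of the 8 largest rises. Krt15 (ENSMUSG00000054146, chromosome 11, 100131758 to 100135928) reached 559 ± 63.7 CPM against 198 ± 30.3 (1.495, SE 0.141, adjusted p = 8.62e-07), Krt13 88.9 ± 13.0 against 29.9 ± 6.97 (1.56), Krt16 42.1 ± 7.25 against 11.9 ± 2.31 (1.82), Krt42 22.0 ± 2.04 against 5.30 ± 1.64 (2.03) and Krt19 16.3 ± 2.46 against 4.61 ± 0.588 (1.83). All of these keratins lie in the type I keratin cluster of chromosome 11, where 5 of 8 tested keratins rose. Krt19 was the 1 call among 3 tested epithelial markers. The other 3 of these 8 were Fbln7 (1.61), the oestrogen-responsive Greb1 (1.59) and Rapgef4 (1.56).

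**Figure D2:**
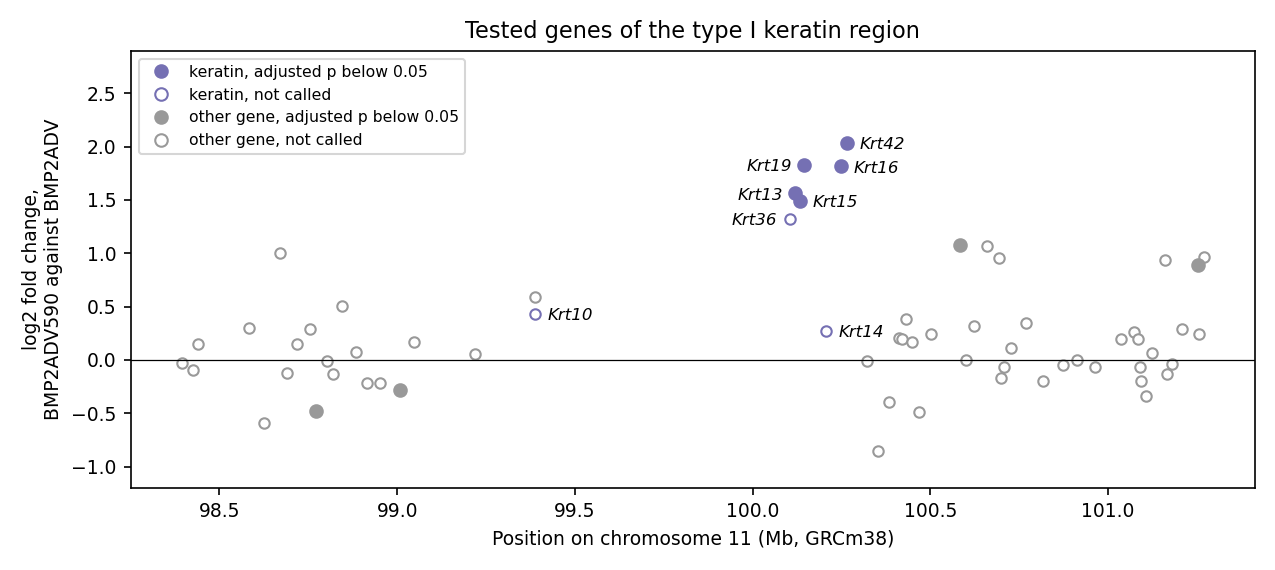
Each point is a tested gene of the type I keratin region and the 1 Mb around it, with its position on chromosome 11 (Mb, GRCm38) and its log2 fold change in BMP2ADV590 against BMP2ADV; filled points passed an adjusted p of 0.05. The keratins have a median of 1.53 and the 56 other genes a median of 0.0699.

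Inflammatory genes fell with miR-590 as well: 9 of 16 NF-kB genes, with none higher and 10 lower adjusted over the list alone (median -1.22, camera adjusted p = 1.43e-10, adjusted p = 0.0641 with an estimated correlation). Ccl2 dropped from 26.8 ± 1.46 to 3.70 ± 1.07 CPM (-2.84, SE 0.229, adjusted p = 1.18e-07), and Ccl7 (-1.76), Tnfaip3 (-2.14) and Ccl5 (-1.201) fell with it. Of 29 interferon response genes, 17 fell and none rose, and adjusted over the list alone 24 were lower and 1 higher (median -0.40, camera adjusted p = 1.39e-11, adjusted p = 0.128 with an estimated correlation). The number that fell was 6 and 11 without BMP2ADV replicate 2 and 3, and 11 and 10 without BMP2ADV590 replicate 1 and 3. Mx2 fell from 136 ± 9.95 to 62.9 ± 10.7 CPM (-1.11, SE 0.123, adjusted p = 4.76e-06) and Rsad2 from 53.02 ± 3.89 to 21.7 ± 3.27 (-1.28, SE 0.159, adjusted p = 1.56e-05), with Mx1 (-1.14) and Cxcl10 (-1.05) also lower. Of 10 MHC class I genes edgeR called 0 (4 at an unadjusted p under 0.05; 0 by DESeq2 and by limma-voom; camera adjusted p = 0.152).

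Genes of the dividing cell were lower. Of 18 mitosis genes, 6 fell and none rose, with 15 lower adjusted over the list alone (median -0.27, camera adjusted p = 1.24e-07, adjusted p = 0.0641 with an estimated correlation). The kinase gene Aurka (-0.40), the cyclin gene Ccna2 (-0.39), Kif20a (-0.35) and Tpx2 (-0.34) were among them. Of 20 DNA replication genes 4 fell (Gins2 -0.59, Cdt1 -0.33, Rrm1 -0.31 and Mcm7 -0.29), with 12 lower adjusted over the list alone (median -0.25, camera adjusted p = 1.23e-06, adjusted p = 0.096 with an estimated correlation). Of these 8 genes, only Aurka and Gins2 kept the call whichever library was left out, and the highest adjusted p of the others was 0.188. Mitosis genes that fell numbered 2, 1 and 3 without BMP2ADV replicate 2, BMP2ADV replicate 3 and BMP2ADV590 replicate 1, and replication genes 2, 1 and 2 without BMP2ADV replicate 2, BMP2ADV replicate 3 and BMP2ADV590 replicate 3. The cyclin D1 gene Ccnd1 fell from 615 ± 54.8 to 377 ± 39.2 CPM (-0.70, SE 0.0879, adjusted p = 1.56e-05) and was the 1 call among 10 Wnt targets (camera adjusted p = 0.298). Of 18 p53 response genes 5 fell, with 8 lower adjusted over the list alone (median -0.27, camera adjusted p = 0.000127, adjusted p = 0.096 with an estimated correlation): the death receptor gene Fas (-0.61), Bbc3 (-0.67), Mdm2 (-0.59), Plk2 (-0.40) and, named after its values were seen, Ccng1 (-0.29). The histone H1 gene Hist1h1e (-1.40), the cystine transporter gene Slc7a11 (-1.44), Serpinb9b (-1.53), Rnd1 (-1.43), Arhgap22 (-1.41) and Noct (-1.37) were among the largest falls.

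Stress genes went both ways: in the unfolded protein response list (18 tested) the chaperone gene Calr (0.39) and Dnajc3 rose, while Ddit3, Atf3 (-1.59), Trib3 (-0.69) and Chac1 (-0.73), which act in the branch that answers amino acid shortage, fell. The list was not called (camera adjusted p = 0.991) and its mean (-0.09) and median (0.03) differ in sign. Contractile fibroblast genes were lower (2 of 9, Lmod1 -0.65 and Tpm2 -0.35, with 4 lower adjusted over the list alone, median -0.25, camera adjusted p = 0.00711, adjusted p = 0.096 with an estimated correlation), though both genes lost the call without some libraries (up to 0.0984 and 0.175). The cholesterol synthesis list was higher as a whole (19 tested, median 0.12, camera adjusted p = 0.00711, adjusted p = 0.096 with an estimated correlation). The list lost its call without BMP2ADV replicate 2 (0.0685). Mitochondrial transcripts were higher: 3 of 7, mt-Nd4 (0.42), mt-Nd2 (0.38) and mt-Cytb (0.30), and 5 adjusted over the list alone (median 0.26, camera adjusted p = 0.0178, adjusted p = 0.418 with an estimated correlation; lost without 8 of the libraries, up to 0.203, and with fry, 0.0913, the 1 list call of BMP2ADV590 of 13 that fry did not keep). None of these 3 was called without BMP2ADV replicate 2 or 3 or BMP2ADV590 replicate 1 (up to 0.197). Their share of gene counts was 2.09 ± 0.214% in BMP2ADV590 and 1.85 ± 0.0967% in BMP2ADV. In the immediate early list Atf3 was the 1 gene called of 11, and the list was lower (median -0.19, camera adjusted p = 0.0446, adjusted p = 0.239 with an estimated correlation; lost without 9 of the libraries, up to 0.204), with 1 higher and 4 lower adjusted over the list alone.

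Fat and sugar metabolism genes were called singly. The fatty acid enzyme genes Scd1 (0.76) and Fasn (0.42) rose in the adipocyte list (8 tested, camera adjusted p = 0.0997). Among 16 hypoxia and glycolysis genes the glucose transporter gene Slc2a1 (0.51), Aldoa (0.27) and P4ha2 (0.29) rose and Hk2 (-0.66) fell (camera adjusted p = 0.345). Aldoa lost its call without BMP2ADV replicate 2 or 3 or BMP2ADV590 replicate 1 (up to 0.164) and P4ha2 without 9 of the libraries (up to 0.174). In the lysosome list (16 tested, camera adjusted p = 0.237, mean -0.10 and median 0.13) Ctsd rose by 0.25, Sqstm1 fell by 0.41 and Gpnmb went from 1.58 ± 0.637 to 0.173 ± 0.241 CPM, with the calls of Ctsd and Gpnmb lost without 6 and 4 of the libraries (up to 0.17 and 0.136). Of 8 Notch targets Hey1 rose and Hes1 (-0.35) fell (camera adjusted p = 0.332), the latter not called without BMP2ADV replicate 3 (0.0709). Of 12 TGF-beta targets Postn (0.30) rose and Bhlhe40 (-0.61) fell (camera adjusted p = 0.619, median -0.07 and mean 0.01), calls lost without 4 and 2 of the libraries (up to 0.14 and 0.0703). Among 22 ribosomal protein genes edgeR called 0, with 1 at an unadjusted p under 0.05 and 0 by DESeq2 and by limma-voom (camera adjusted p = 0.739). Markers of other cell types were few: 2 muscle, 4 macrophage, 4 endothelial, 3 epithelial and 4 neural genes were tested, of which the muscle genes Tnni1 (0.64) and Acta1 (-0.53), Krt19 and the neural Map2 (-0.54) were called, Acta1 not without 9 of the libraries (up to 0.177). Adjusted over the list alone, the adipocyte list had 3 genes higher, hypoxia and glycolysis 4 higher and 2 lower, lysosome 2 and 2, Notch 3 and 2, TGF-beta 2 and 1, unfolded protein response 6 and 4, BMP pathway 6 and 1, matrix remodelling 4 and 4, and Wnt 1 lower. Of the 86 named genes called in BMP2ADV590, 60 kept the call under the alternatives run.

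**Figure D3:**
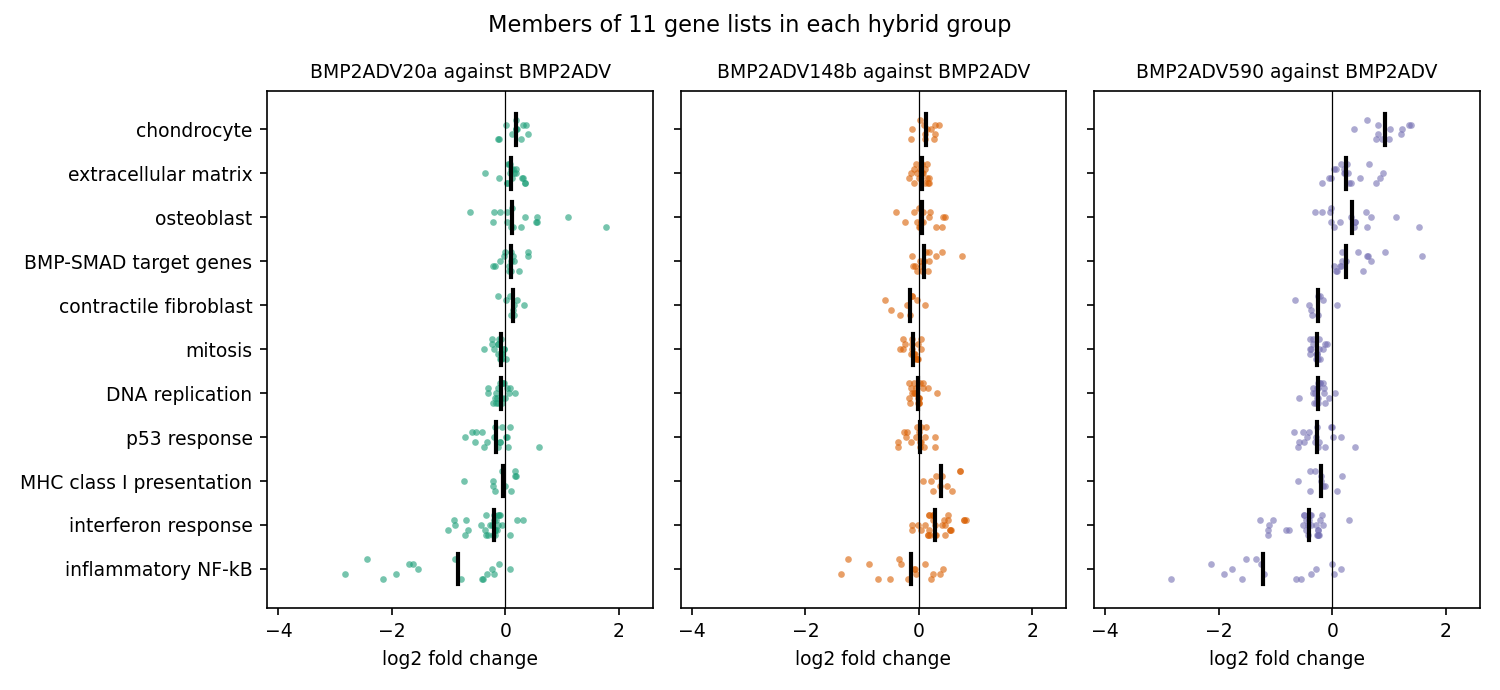
Log2 fold change against BMP2ADV of each tested member (points) of 11 gene lists in the 3 hybrid groups, with the list median as a black bar. Interferon response medians were -0.21 in BMP2ADV20a, 0.29 in BMP2ADV148b and -0.40 in BMP2ADV590, and the chondrocyte median was 0.93 in BMP2ADV590.

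Placed side by side, miR-20a and miR-148b cells differed in antiviral and inflammatory genes. In BMP2ADV20a, Cxcl10 stood at 26.4 ± 5.73 CPM against 86.4 ± 30.2 in BMP2ADV148b (-1.71, SE 0.178, adjusted p = 4.7e-06), with Mx1 (-1.58), Rsad2 (-1.53) and Ccl7 (-1.48) lower as well. Of 29 interferon response genes 14 were lower and none higher, with 27 lower adjusted over the list alone (median -0.52, camera adjusted p = 7.43e-31, adjusted p = 0.0515 with an estimated correlation). Of 10 MHC class I genes 4 were lower, with 6 adjusted over the list alone (median -0.54, camera adjusted p = 2.36e-09, adjusted p = 0.115 with an estimated correlation). NF-kB genes were lower (4 of 16, 8 adjusted over the list alone, median -0.66, camera adjusted p = 2.67e-12) and contractile genes higher (2 of 9, Actg2 0.53 and Tpm2 0.43, 7 adjusted over the list alone, median 0.31, camera adjusted p = 3.68e-06). Both held with an estimated correlation (adjusted p = 0.0412 each). Unfolded protein response and p53 response genes were lower (medians -0.19 and -0.18) and extracellular matrix genes higher (0.12), with camera adjusted p of 7.88e-05, 0.00134 and 0.0184 and adjusted p = 0.115, 0.129 and 0.557 with an estimated correlation. In them edgeR called 1, 2 and 0 genes, and adjusted over the list alone 6 lower, 2 lower with 1 higher, and 0; of the matrix genes 3 had an unadjusted p under 0.05, DESeq2 and limma-voom called 0, and fry did not call the list (adjusted p = 0.319). Pofut1 (0.52), Anxa8 (0.51) and Pdia3 (0.39) were higher, but like Actg2 and Tpm2 they lost the call without BMP2ADV20a replicate 1 (up to 0.377). In all, 7 genes were higher and 67 lower in BMP2ADV20a, of 1031 with an unadjusted p under 0.05. The count was 22 and 42 without BMP2ADV20a replicate 1 and 3, and 24 and 48 without BMP2ADV148b replicate 1 and 2.

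Against BMP2ADV20a, the BMP2ADV590 cells had more cartilage transcripts. Of 12 chondrocyte genes 8 were higher, with 12 adjusted over the list alone (median 0.82, camera adjusted p = 4.36e-10, adjusted p = 0.215 with an estimated correlation), such as Col9a1 at 70.2 CPM against 32.2 (1.13, SE 0.206, adjusted p = 0.00426). BMP-SMAD targets were higher (4 of 15, 4 adjusted over the list alone, median 0.34, camera adjusted p = 0.000136, adjusted p = 0.202 with an estimated correlation) and contractile genes lower (4 of 9, 6 adjusted over the list alone, median -0.41, camera adjusted p = 2.97e-06), a call that held with an estimated correlation (adjusted p = 0.0482). Plagl1 (ENSMUSG00000019817, chromosome 10), an imprinted zinc finger gene, stood at 74.3 ± 10.3 CPM against 29.9 ± 8.10 (1.32, SE 0.2, adjusted p = 0.00134), and the matrix proteoglycan gene Lum (1.26), Cmtm5 (1.17) and Krt42 (1.13) were higher. Hist1h1e (-1.24), Fhl1 (-0.90), Tuba4a (-0.89), Ccl5 (-0.88) and Arhgdib (-0.87) were lower. Of 29 interferon response genes edgeR called 0 (10 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma-voom), with 2 lower adjusted over the list alone and a median of -0.14 (camera adjusted p = 0.000623, adjusted p = 0.562 with an estimated correlation and 0.29 with fry). The NF-kB list was not called (median -0.10 and mean 0.0152, camera adjusted p = 0.12). Mitosis (-0.18) and DNA replication (-0.15) genes were lower and cholesterol synthesis (0.09), adipocyte (0.27) and extracellular matrix (0.10) genes higher, with camera adjusted p of 9.12e-05, 0.000146, 0.0156, 0.0217 and 0.0217 and adjusted p = 0.145, 0.226, 0.215, 0.226 and 0.451 with an estimated correlation. The matrix list was not called by fry (adjusted p = 0.121). In these lists edgeR called 0, 1, 0, 2 and 4 genes, with 0, 1, 0, 3 and 5 adjusted over the list alone; mitosis and cholesterol synthesis had 8 and 4 genes at an unadjusted p under 0.05, 2 and 0 by DESeq2 and 0 each by limma-voom. In all, 171 genes were higher and 116 lower, of 1901 with an unadjusted p under 0.05. The count was 64 and 85 without BMP2ADV20a replicate 1 and 2, 150, 489 and 147 without BMP2ADV590 replicate 1, 2 and 3, and Lum, Cmtm5 and Arhgdib lost their calls without BMP2ADV20a replicate 1 or 2 (up to 0.0804, 0.0771 and 0.0844), Arhgdib also without BMP2ADV590 replicate 1 or 3, and Ccl5 without BMP2ADV20a replicate 2 (0.0665).

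The interferon list differed most, by its median, between BMP2ADV590 and BMP2ADV148b. Of 29 interferon response genes 25 were lower in BMP2ADV590 and none higher, with 28 lower adjusted over the list alone (median -0.70, camera adjusted p = 1.71e-28, adjusted p = 0.0951 with an estimated correlation). Rsad2 (-2.10, SE 0.159, adjusted p = 1.44e-08), Cxcl10 (-1.85) and Mx1 (-1.71) were among them, and Ccl2 was lower too (-2.12). MHC class I genes (6 of 10, 6 adjusted over the list alone, median -0.64, camera adjusted p = 7.29e-09) and NF-kB genes (7 of 16, 11 adjusted over the list alone, median -0.70, camera adjusted p = 2.07e-10) were lower too, each with adjusted p = 0.0951 with an estimated correlation. Chondrocyte genes (8 of 12, 12 adjusted over the list alone, median 0.86, camera adjusted p = 2.07e-10) and extracellular matrix genes (6 of 18, 10 adjusted over the list alone, median 0.20, camera adjusted p = 2.72e-05) were higher, each with adjusted p = 0.108 with an estimated correlation. Krt42 (1.51), Rapgef4 (1.39), Krt16 (1.33), Greb1 (1.30) and Plagl1 (1.30, 74.3 against 30.3 CPM) were the 5 largest rises among called genes with at least 10 CPM and no overlap between libraries. BMP-SMAD (0.23) and osteoblast (0.24) genes were higher and DNA replication (-0.25), p53 response (-0.24), mitosis (-0.19) and unfolded protein response (-0.15) genes lower, with camera adjusted p of 0.000528, 0.0226, 1.45e-06, 4.46e-05, 9.39e-05 and 0.0131; none of them held with an estimated correlation (lowest adjusted p = 0.0951). Of these lists, edgeR called 2 BMP-SMAD, 3 DNA replication and 2 p53 response genes, all in the direction of the list, and 1 higher and 2 lower unfolded protein response genes, with 5, 8, 8 and 1 and 3 adjusted over the list alone. It called 0 osteoblast and 0 mitosis genes, with 3 and 9 at an unadjusted p under 0.05, 1 and 3 by DESeq2, 1 and 0 by limma-voom and 1 and 6 adjusted over the list alone. In all, 325 genes were higher and 261 lower, of 2261 with an unadjusted p under 0.05. The count was 241 and 353 without BMP2ADV148b replicate 1 and 2 and 383 without BMP2ADV590 replicate 3.

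**Figure D4:**
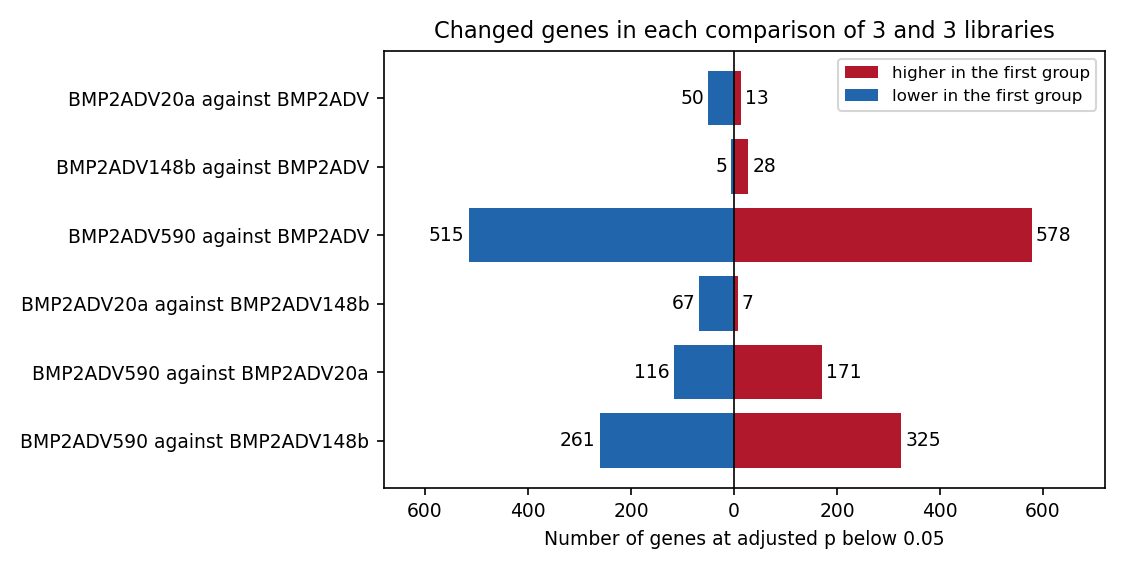
Number of genes with an edgeR adjusted p under 0.05 in each of the 6 comparisons, higher and lower in the first group. The comparisons with BMP2ADV590 hold 1093, 287 and 586 called genes, the other 3 comparisons 63, 33 and 74.

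Tested over all 4 groups at once, 827 genes differed, of 2537 with an unadjusted p under 0.05. Without BMP2ADV590 replicate 3 the number was 548. The lists of called genes overlapped: 13 genes were higher and 43 lower in both BMP2ADV20a and BMP2ADV590 than in BMP2ADV, and none went opposite ways. BMP2ADV20a and BMP2ADV148b shared 2 higher and 2 lower genes with 2 opposite, and BMP2ADV148b and BMP2ADV590 shared 8 higher and 3 lower genes with 6 opposite. These pairs use the same BMP2ADV libraries. In simulated data without any change, the shared reference alone correlated the fold changes across genes. The correlation between BMP2ADV20a and BMP2ADV590 was 0.508 there, against 0.534 observed. It was 0.4985 against 0.4628 observed for BMP2ADV20a and BMP2ADV148b, and 0.493 against 0.4309 for BMP2ADV148b and BMP2ADV590. The observed covariance was above the simulated one in each of these pairs. It was 0.0771 against 0.0379 simulated for BMP2ADV20a and BMP2ADV590 and 0.0555 against 0.0378 for BMP2ADV20a and BMP2ADV148b. For BMP2ADV148b and BMP2ADV590 it was 0.0619 against 0.0376. The lower correlations thus do not show that these groups shared less than the reference alone gives. Genes are not independent replicates. The simulations seldom gave shared calls, with a mean of 0.1 higher and 0 lower genes for BMP2ADV20a and BMP2ADV590. Since no gene was changed in them, few genes could be called at all. They therefore cannot show how many shared calls a common reference gives when many genes change. Contrasts with no library in common, BMP2ADV20a against BMP2ADV and BMP2ADV590 against BMP2ADV148b, had 9 genes higher and 25 lower in both, where independent lists would share 0.319 and 0.987, and a correlation across genes of 0.152 against 0.00152 in simulated data. A further such pair was BMP2ADV590 against BMP2ADV and BMP2ADV20a against BMP2ADV148b. It had 1 gene higher and 42 lower in both, where independent lists would share 0.306 and 2.61. Its correlation was 0.102 against 0.0043 in simulated data.

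The miRNAs themselves pair with short sites in the 3' ends of transcripts, and genes with such sites were compared with all others. In BMP2ADV148b the 1826 genes with a site for miR-148b-3p (TGCACTG) differed in median log2 fold change from the other genes by -0.0344, with a camera p of 0.0298 that missed the threshold over the 12 tests (adjusted p = 0.179). The same sites gave -0.0197 in BMP2ADV590 (adjusted p = 0.731) and -0.00752 in BMP2ADV20a (adjusted p = 0.768). The shift of miR-148b-3p site genes in BMP2ADV148b against BMP2ADV had a camera p of 0.059 without BMP2ADV replicate 2 and of 0.0724 without BMP2ADV148b replicate 1, while with any 1 library left out its size ran from -0.0470 to -0.0348. With 8-mer sites only (505 genes) it was -0.0761 with a camera p of 0.000178. For miR-20a-5p sites (GCACTTT, 1744 genes) in BMP2ADV20a the difference was -0.0140 (adjusted p = 0.731). In BMP2ADV590 it was -0.00993 for miR-590-5p sites (ATAAGCT, 949 genes, adjusted p = 0.787) and -0.0312 for miR-590-3p sites (TAAAATT, 2877 genes, adjusted p = 0.651). Sites for miR-590-3p also gave -0.0442 in BMP2ADV20a (adjusted p = 0.179) and -0.0292 in BMP2ADV148b (adjusted p = 0.192), groups that lack that miRNA on the plasmid. Of 125 random 7-mers, 21.6%, 26.4% and 29.6% gave a shift as low as miR-590-3p sites in BMP2ADV20a, BMP2ADV148b and BMP2ADV590. Of 1000 random 7-mers, 30.4% were as low as miR-20a-5p sites in BMP2ADV20a and 74.7% as low as miR-590-5p sites in BMP2ADV590. For miR-148b-3p sites in BMP2ADV148b, 0 of 1000 were as low.

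No list of candidate targets, taken from general knowledge, was called by camera in the group of its own miRNA. Of 19 candidate targets of miR-20a, edgeR called 0 in BMP2ADV20a (1 at an unadjusted p under 0.05, 0 by DESeq2, by limma-voom or adjusted over the list alone; median 0.06, camera adjusted p = 0.682). Of 14 candidate targets of miR-148b, edgeR called 0 in BMP2ADV148b (2 at an unadjusted p under 0.05, 0 by DESeq2 and by limma-voom, 2 lower adjusted over the list alone; median 0.00, camera adjusted p = 0.53). Of 11 candidate targets of miR-590-5p, 2 were higher in BMP2ADV590, Pdcd4 (0.56) and Timp3 (0.58), and none lower, with 2 higher and 1 lower adjusted over the list alone (median 0.14, camera adjusted p = 0.302). By fry this list was higher in BMP2ADV590 than in BMP2ADV (adjusted p = 0.0415), BMP2ADV20a (0.0321) and BMP2ADV148b (0.0263). Among the other lists in BMP2ADV590, Bambi, Bmpr2 and Limk1 (0.41) rose and Ccnd1 fell in the miR-20a list (19 tested, camera adjusted p = 0.345), and Nog and the cholesterol exporter gene Abca1 (0.77) rose and Csf1 (-1.05) fell in the miR-148b list (14 tested, camera adjusted p = 0.944). Limk1 and Abca1 each lost the call without 4 of the libraries (up to 0.157 and 0.218). Of the genes always named, those often linked to these miRNAs were not called in their own group. In BMP2ADV20a, Pparg, the master regulator of fat cells, had a log2 fold change of -0.52 (95% interval -1.10 to 0.07, adjusted p = 0.567), Bambi of 0.10 (-0.18 to 0.38) and Crim1 of 0.16 (-0.06 to 0.38). In BMP2ADV148b, Nog had 0.76 (-0.28 to 1.80, adjusted p = 0.723), and in BMP2ADV590 the inhibitory Smad7 had 0.09 (-0.15 to 0.33, adjusted p = 0.728).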

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

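The tests of depth, of 3' UTR length and of site number were set before their results were seen; those of Gm42418 and mitochondrial genes, of a BMP2ADV shift, of plasmid uptake, of epithelial cells and, in its present form, of the keratin region were chosen only after the result was seen.

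Interferon response genes moved in opposite directions in different hybrid groups, which was tested on the difference itself. The list median was -0.523 in BMP2ADV20a against BMP2ADV148b (medians -0.207 and 0.291 against BMP2ADV, adjusted p = 0.0515 with an estimated correlation). It was -0.701 in BMP2ADV590 against BMP2ADV148b (-0.403 and 0.291, adjusted p = 0.0951 with an estimated correlation). Each difference passed camera with the preset correlation (adjusted p = 7.43e-31 and 1.71e-28).

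For the lower interferon genes in BMP2ADV590, thinning all libraries to the smallest total gave a list median of -0.408, against -0.403 at full depth. This cannot decide on depth, since the scaling already divides out library totals, so thinning could hardly move the median. The libraries summed to 35572113 gene counts in BMP2ADV590 and 33469711 in BMP2ADV. Without Gm42418 and the mitochondrial genes the list median was -0.409. That cannot decide on a few dominant genes either, since TMM scaling already limits their weight. A shift of the BMP2ADV libraries stays open: without them the median was -0.141 against BMP2ADV20a (adjusted p = 0.000623, and 0.562 with an estimated correlation) and -0.701 against BMP2ADV148b, and each of those groups has its own change. Less plasmid in the BMP2ADV590 cells, which might give a weaker antiviral response, stays open too: Bmp2 was higher by 1.91, but where its reads come from is unknown. An effect of the miR-590 insert is the biological explanation the design offers, and it was not tested apart from other differences between the plasmids or cultures.

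For the type I keratins in BMP2ADV590, epithelial cells as the source of the rise are argued against by Krt5 and Krt14, abundant in keratinocytes. These differed together by 0.474 CPM while Krt15 differed by 360.9. Other epithelial genes differed little. Against BMP2ADV, Jup (5.982 ± 0.2962 against 7.809 ± 1.122 CPM), Cdh1 (1.495 ± 0.5398 against 2.099 ± 0.2782) and Trp63 (1.141 ± 0.3162 against 1.499 ± 0.5529) had lower means. Krt10 (10.08 ± 2.657 against 7.463 ± 0.434) and Dsp (0.09411 ± 0.163 against 0) had higher means. Jup and Krt10 were not called by edgeR (adjusted p = 0.331 and 0.278), and the other levels were low, so these directions decide nothing. Krt8, Krt18 and Cldn4 were at 0 CPM in both groups and Epcam at 0 against 0.1725, so these cannot separate the groups. A change of the whole chromosome 11 region is argued against by the 56 other tested genes within 1 Mb, whose median was 0.0699 against 1.53 for the 8 keratins, with quartiles of -0.121 and 0.287 and with 2 of them higher and 2 lower. A regulated rise of keratin genes in these cells may therefore be the explanation, as a hypothesis found and tested on the same data.

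For the lower genes with miR-148b-3p sites in BMP2ADV148b, 3' UTR length and base composition are argued against: within strata of both, the difference was -0.0313 and the permutation p of 1e-04 is the smallest that 10000 permutations can give. Repression through the site would lower genes with at least 2 sites further, and their median differed by -0.0403 from that of genes with 1 site (permutation p = 0.0043). That test was not matched for 3' UTR length or base composition, so it cannot tell repression from either. Among 1000 random 7-mers, 0 gave a shift as low as that of all site genes. But in BMP2ADV590, whose plasmid was not built to carry this miRNA, 2.6% of random 7-mers gave a shift as low as that of these sites. Of the site genes called in BMP2ADV148b 3 were higher and 0 lower. Only 5 of all 33 genes called there were lower, too few for this count to decide anything. A shift of the BMP2ADV libraries stays open too. Against the mean of the other hybrids the difference was -0.0168 (permutation p = 3e-04), against -0.0344 with BMP2ADV as the reference. That fall in size met the rule for such a shift, a rule chosen only after the result was seen. Genes are not independent replicates in these permutations; with 1 library left out the shift ran from -0.0470 to -0.0348, and the shift of miR-148b-3p site genes in BMP2ADV148b against BMP2ADV had a camera p of 0.059 without BMP2ADV replicate 2 and 0.0724 without BMP2ADV148b replicate 1. Repression by the miRNA may thus be part of the explanation, and a direct measurement of mature miR-148b was not analysed here.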

How the results depend on the processing

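The removal of Gm42418 and mitochondrial genes, and leaving out libraries for gene lists and seed sites, were chosen only after the data had been seen. Numbers of called genes stayed within 1.5 times under RLE and upper-quartile scaling, limma-voom, the stricter filter and without Gm42418 and mitochondrial genes. Beyond that, against BMP2ADV the 63 genes of BMP2ADV20a became 107 with DESeq2 (62 kept), 184 without a filter (63 kept) and 145 when only those groups were fitted, and the 33 of BMP2ADV148b became 85 with DESeq2 (31 kept) and 126 without a filter (33 kept). Without a filter the counts were 137 for BMP2ADV20a against BMP2ADV148b and 519 for BMP2ADV590 against BMP2ADV20a. The cause was not tested. With a replicate block they were 36, 14 and 905 for the hybrids against BMP2ADV, 58 for BMP2ADV20a against BMP2ADV148b, and 172 and 460 for BMP2ADV590 against BMP2ADV20a and BMP2ADV148b. The replicate numbers gave no sign of pairing. Once each group's mean was removed, the correlation over 18 pairs of equal number in different groups ran from -0.113 to 0.0715. Of 12 libraries, 1 was closest to its own number.

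Leaving out 1 library, which also leaves fewer samples, gave 18 to 108 genes for BMP2ADV20a against BMP2ADV, 3 to 60 for BMP2ADV148b, 565 to 1115 for BMP2ADV590, 22 to 93 for BMP2ADV20a against BMP2ADV148b, 64 to 489 and 241 to 656 for BMP2ADV590 against BMP2ADV20a and BMP2ADV148b, and 548 to 891 over 4 groups. Shifts of site genes ran from -0.0142 to -0.00766 for miR-20a-5p, from -0.0470 to -0.0348 for miR-148b-3p, from -0.0521 to -0.0163 for miR-590-3p and, changing sign without BMP2ADV replicate 2 or BMP2ADV590 replicate 2, from -0.0213 to 0.000924 for miR-590-5p. With 8-mer sites only, the shift of miR-148b-3p site genes in BMP2ADV148b against BMP2ADV was -0.0761 and the shift of miR-590-3p site genes in BMP2ADV590 against BMP2ADV was -0.0145. For miR-590-5p sites in BMP2ADV148b the range was -0.0197 to 0.00508.

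An estimated correlation kept 1 of the 28 list calls against BMP2ADV, the replicate block 26 and no filter 26. Fry, which does not compare a list with other genes, kept 3 of 9 in BMP2ADV20a, 0 of 6 in BMP2ADV148b and 12 of 13 in BMP2ADV590. No named gene that was called changed direction. Uncalled genes that changed sign, for causes that were not tested, did so when 1 library was left out. In BMP2ADV20a against BMP2ADV, log2 fold changes ran from -0.36 to 0.46 for Mir17hg (0.10 with limma-voom), from -0.0553 to 0.22 for Bambi and from -0.0243 to 0.81 for Nog. In BMP2ADV148b against BMP2ADV they ran from -0.0843 to 0.0018 for Eif4h, from -0.0282 to 0.12 for Pparg, from -0.0067 to 0.13 for Smad7 and from -0.0593 to 0.21 for Bambi. In BMP2ADV590 against BMP2ADV they ran from -0.65 to 0.21 for Mir17hg and from -0.35 to 0.34 for Pparg. In simulated data at this depth 33 of 67 genes changed 1.5-fold were called.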

Other observations

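The lists of imprinted and histone genes were drawn up only after Plagl1 and Hist1h1e had been seen to change, and their tests and the splits were fixed before their own results were seen.

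A pair of imprinted genes besides Plagl1 rose in BMP2ADV590 against BMP2ADV. Dlk1, which encodes a membrane protein of preadipocytes and fetal tissue, had a log2 fold change of 1.201 (adjusted p = 0.000548), and Gnas, which encodes a G protein subunit, 0.44 (adjusted p = 0.00354). They were named after their values were seen and were the 2 higher of 19 imprinted genes tested without Plagl1, none of which was lower. A hypothesis is that imprinted genes as a set may be higher in this group. The median was 0.171, with camera p = 0.0366 at the preset correlation and p = 0.0528 with an estimated one, so the question stays open.

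Histone cluster genes without Hist1h1e had a median of -0.458 in BMP2ADV590 against BMP2ADV, with camera p = 0.0277 at the preset correlation and p = 0.128 with an estimated one. Of the 30 tested, edgeR called 0, with 4 at an unadjusted p under 0.05 and 0 called by DESeq2 and by limma-voom. That histone genes as a set may be lower in this group stays open as well.

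Regrouping the 6 libraries of a comparison gives 10 splits, too few for a share under 0.05, and in each comparison 1 of the 10, the real one, gave as many called genes. The real and the highest other count were 63 and 0 for BMP2ADV20a against BMP2ADV, 33 and 0 for BMP2ADV148b, 1093 and 1 for BMP2ADV590, 74 and 0 for BMP2ADV20a against BMP2ADV148b, 287 and 30 for BMP2ADV590 against BMP2ADV20a, and 586 and 6 for BMP2ADV590 against BMP2ADV148b. Over all 4 groups, 1 of 100 splits of the 12 libraries, the real one, reached 827 genes and the highest other reached 220. That argues against chance assignment of libraries to groups for that count only if the libraries are independent. The labels do not say whether they are separate cultures, so the splits cannot tell the plasmid from a difference between cultures.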
